A study of Homo sapiens with 3 samples.

How the data were processed

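Single-cell RNA sequencing was done on cryopreserved and thawed bone marrow mononuclear cells of 2 donors, each sampled at MDS and at sAML. Donor B gave 1 library per stage, made with a 5′ droplet kit in separate lanes of the same chip and sequenced together. Donor A gave 1 library made with a 3′ kit, in which both stages carried antibody hashtags and shared a lane. Sequencing was on an Illumina NovaSeq instrument. The deposited values are raw UMI counts per feature and cell barcode, made with Cell Ranger, per the file headers in version 3.1.0 for donor B and 6.0.2 for donor A, whereas the submitters' processing notes name Cell Ranger 3.1 and the GRCh38 genome for every library. UMIs are molecular identifiers that collapse copies of a molecule made by PCR. The deposited barcodes had been filtered to called cells, since no barcode held fewer than 500 RNA UMIs.

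The MDS library of donor B held 5114 barcodes with 26598241 RNA UMIs (median 3584.5 per barcode), the sAML library 4492 barcodes with 21834007 UMIs (median 2747.5) and the donor A pool 23228 barcodes with 136246154 RNA UMIs (median 3441) and 52126174 antibody UMIs over 31 surface tags and 6 hashtags. Each donor B library also listed 26 antibody and hashtag features, which held 742 and 1090 UMIs in all and were not used in a comparison. Barcodes were kept with at least 300 genes and at most 20% mitochondrial UMIs. In MDS 29.3% of the barcodes exceeded the mitochondrial limit, in sAML 15.0% and in the pool 20.9%. Doublets were scored with Scrublet in scanpy. Its own threshold marked 7 MDS barcodes and 0 sAML barcodes, so the barcodes with the highest scores were removed at a rate of 0.8% per 1000 barcodes, a choice made after the scores were seen. That rate was 4.09% in MDS (186 barcodes), 3.59% in sAML (159) and 18.6% in the pool (4079). In the pool, 3567 barcodes above the threshold of more than 1 hashtag were removed as well. The kept cells were 3431 in MDS (22736936 UMIs, median 5606), 3634 in sAML (19920207 UMIs, median 3357.5) and 12886 in the pool (81235291 UMIs, median 3765).

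Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were scaled with a cap of 10 and reduced to 30 principal components, rounded to 3 decimals. Genes in fewer than 10 cells and mitochondrial, ribosomal, immunoglobulin, T cell receptor, HLA and sex-linked genes and MALAT1 were left out of that step. Leiden clusters were found on 15 neighbours at resolution 1.0 with 10 iterations and seed 1. The donor B libraries were clustered together without integration and the pool alone. A cluster took the name of the class with the highest mean log2 fold over its markers, among 17 marker lists, with an offset of 10 CPM. A name required 3 markers detected in at least 10% of the cells, a score of at least 0.5, a margin of 0.5 over the next class, and no larger number of another class's markers among the 10 leading genes. A cluster whose median UMIs were under 1/3 of the library median also needed a marker among its leading genes. Other clusters stayed unnamed. Names end in "-like" because they rest on RNA markers alone.

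The comparison of stages used donor B. A class was compared where both libraries had at least 50 of its cells, which left out B-like, erythroid-like, mast-or-basophil-like, megakaryocyte-like and plasmacytoid-dendritic-like cells. Shares carry exact Clopper-Pearson 95% intervals and their differences Newcombe intervals. A count of 0 is given with the limit that 3 counts allow. UMIs were summed per library and class and scaled to CPM with exact Poisson 95% intervals, and the log2 ratio of sAML over MDS carries an exact conditional interval. A gene was measured with at least 50 UMIs over both libraries. It was counted as higher or lower where its log2 ratio was at least 1 in size and the Poisson intervals were apart. With 1 library per stage no test was run and no p-value is given.

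Before the data were examined, the marker lists, 26 gene lists, the naming rule, the comparisons and the first group of alternative settings were fixed. Named genes had at least 50 CPM in the higher library and intervals apart, and were the 10 largest and 10 smallest ratios in progenitor-like cells and 5 and 5 in the other classes. Mitochondrial, ribosomal, immunoglobulin and T cell receptor segment genes, sex-linked genes of the Y chromosome and of X inactivation, HLA genes outside the MHC class II list, and names of clones and reading frames were left out. In NK-like cells 1 gene that met the rule was also left out, afterwards, because its family varies in gene content between people, and a few further items that met the rules are not reported. The members described of each list are those with the most UMIs or the largest ratios, and some further members were chosen after their values were seen. A list with at least 5 measured genes is given as its median log2 ratio, with an interval from 200 Poisson bootstrap draws and its percentile among 10000 random lists matched on expression in 20 bins. Gene positions are those of GENCODE on GRCh38.

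The ratio rule was tested on simulated data with the depths of the progenitor-like sums, over 10543 measured genes. It called 44 of 44 genes set to a log2 ratio of -2, 38 of 38 set to -1.5, 48 of 50 set to 1.5 and 50 of 50 set to 2, and 6 of 10361 genes without a difference. The intervals of those unchanged genes covered the set value in 95.4% of cases. Of 200 lists of 12 genes without a shift, 3.5% fell outside the percentiles 2.5 and 97.5, and of 50 lists shifted by 1 log2 unit 100% did. The simulation holds counting error only and no variation between samples.

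In the pool, a hashtag was read as positive above the emptiest bin of its log10 counts within a fixed window, without locating modes. The thresholds were 14.8, 11.6, 24.1, 30.6, 24.1 and 49.1 UMIs for hashtags 1, 2, 3, 4, 5 and 7. For hashtag 7 that bin was the last of the window, so its threshold and values depend on where the window ended. No hashtag was positive in 3887 barcodes, and 15774 had 1. The hashtags are numbered and not named for a stage. The planned edgeR test of stage over both donors therefore was not run, nor were its 4 alternatives, and stages were not guessed from cell content. Copy number, genotype and personal traits were not derived.

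The alternative settings fixed in advance were a mitochondrial limit of 10%, a minimum of 500 genes, doublets kept, resolutions of 0.5 and 2.0, each library clustered alone, TMM factors from edgeR and size factors from DESeq2, a minimum of 20 UMIs or of 1 UMI per gene, and thinning of the deeper class sum. Alternatives added after the data were seen were Scrublet's own threshold, a minimum of 1000 UMIs per cell, unnamed clusters counted with their best class (with joint and with separate clustering, and with the minimum of 1000 UMIs), macrophage-named clusters counted as monocyte-like with the minimum of 500 genes, HSPC-like or myeloid-progenitor-like cells alone, and the pool's megakaryocyte-like share. The work used Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.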

Results

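Bone marrow of 1 donor, here donor B, held more progenitor-like and erythroid-like cells and fewer T-like and dendritic-like cells in secondary acute myeloid leukemia (sAML) than in the preceding myelodysplastic syndrome (MDS). MDS is a clonal disorder of blood formation that can progress to acute leukemia, which is then called secondary. Progenitor-like cells, the sum of cells like hematopoietic stem and progenitor cells (HSPC) and of myeloid-progenitor-like cells, made up 13.9% of the MDS cells and 30.05% of the sAML cells, a difference of 16.2 percentage points (95% interval 14.3 to 18.1). T-like cells made up 25.1% and 3.22%, a difference of -21.9 points (-23.5 to -20.3). Dendritic-like cells made up 15.2% and 1.73%, a difference of -13.4 points (-14.7 to -12.1). These shares come from 3431 MDS and 3634 sAML cells in 1 library per stage, so there are no replicates, no difference between the stages was tested, and every interval and floor given here covers counting error only.

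Most of the larger progenitor-like share lay in the myeloid-progenitor-like cells, which express the granule enzymes of early neutrophil development. They were 5.63% of the MDS cells (193 cells) and 21.0% of the sAML cells (764 cells), a difference of 15.4 points (13.8 to 17.0). A group of these cells led by PRTN3, AZU1, MPO and ELANE, genes of primary granule proteins, made up 4.49% and 12.4%. A cycling group led by UBE2C, MKI67 and TOP2A made up 1.14% and 8.61%. HSPC-like cells were 8.25% and 9.03%, and their difference of 0.778 points had an interval that included 0 (-0.555 to 2.11). That difference depended on the clustering. It was 5.20 points at resolution 0.5, 5.34 points at resolution 2.0 and 10.5 points when unnamed clusters were counted with their closest class. For myeloid-progenitor-like cells these settings gave 20.6, 21.004 and 15.4 points. The myeloid-progenitor-like difference was 27.3 points with doublets kept, 27.2 with Scrublet's own threshold and 0.759 with each library clustered alone. When each library was clustered alone, several sAML progenitor clusters failed the naming rule and the progenitor-like difference was 0.916 points, against 27.6 points once unnamed clusters were counted with their closest class.

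Both main T-like groups made up less of the sAML library. The group led by IL7R and LTB, genes of naive and memory T cells, held 687 MDS cells and 54 sAML cells, or 20.02% and 1.49%. The cytotoxic group led by GZMK, CD8B, CCL5 and CD8A held 175 and 63 cells, or 5.10% and 1.73%. NK-like cells, the cytotoxic lymphocytes of innate immunity, differed less, at 7.23% and 5.39% (difference -1.83 points, -3.00 to -0.682), and by -0.0474 points, 6.27% and 6.22%, with each library clustered alone. B-like cells were few, with 29 cells in MDS and 4 in sAML. Conventional-dendritic-like cells, which present antigen to T cells, were 13.0% and 1.62%, and plasmacytoid-dendritic-like cells, known as producers of type I interferon, were 2.16% (74 cells) and 0.110% (4 cells).

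Monocyte-like cells made up 34.8% of the MDS cells and 39.2% of the sAML cells (difference 4.33 points, 2.06 to 6.59), but their subgroups differed more than their sum. A group led by IFIT2, IFIT3, APOBEC3A and RHOB, of which the IFIT genes and APOBEC3A are interferon-induced, made up 15.3% of the MDS cells and 0.853% of the sAML cells. A group led by S100A8, S100A12 and MCEMP1 made up 3.61% and 13.7%. Its cells held few UMIs, at a median of 0.291 of the library median, against 1.10 to 1.74 in the other monocyte-like groups. The summed monocyte-like difference was -8.62 points when cells with fewer than 500 genes were left out and -2.15 points when cells with fewer than 1000 UMIs were left out, and both signs depended on clusters that took another name or none. It was 1.0051 points with the macrophage-named cluster of the first setting counted in, and 1.13 points with the unnamed clusters of the second counted with their closest class.

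Erythroid-like cells made up 0.670% of the MDS cells (23 cells) and 4.76% of the sAML cells (173 cells), a difference of 4.09 points (3.34 to 4.87). Of these, 3 MDS and 108 sAML cells lay in a group with few UMIs, at a median of 0.390 of the library median. The next score of that group was for myeloid progenitors. The other group held 20 and 65 cells, or 0.583% and 1.79%. In sAML, erythroid-like cells held 788 CPM of MPO and 3071 CPM of S100A8, against 32.9 and 182 CPM in T-like cells. They were thus not free of myeloid RNA. Cells like mast cells or basophils, in a group led by CLC, PRG2, TPSAB1 and HDC, made up 0.700% and 3.05% (difference 2.35 points, 1.72 to 3.02). PRG2 was not among the markers that gave the name. Megakaryocyte-like cells numbered 15 in MDS and 0 in sAML, where a count of 0 allows a share of up to 0.0826%. Unnamed cells were 1.14% of the MDS library and 12.5% of the sAML library. Most of them, 359 of the 455 in sAML, belonged to a group led by GSR, C1QTNF4, NPW and HSPD1 whose marker score came closest to HSPC. That group also held few UMIs, at a median of 0.3565 of the library median, against 2.41 for HSPC-like cells.

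**Figure D1:**
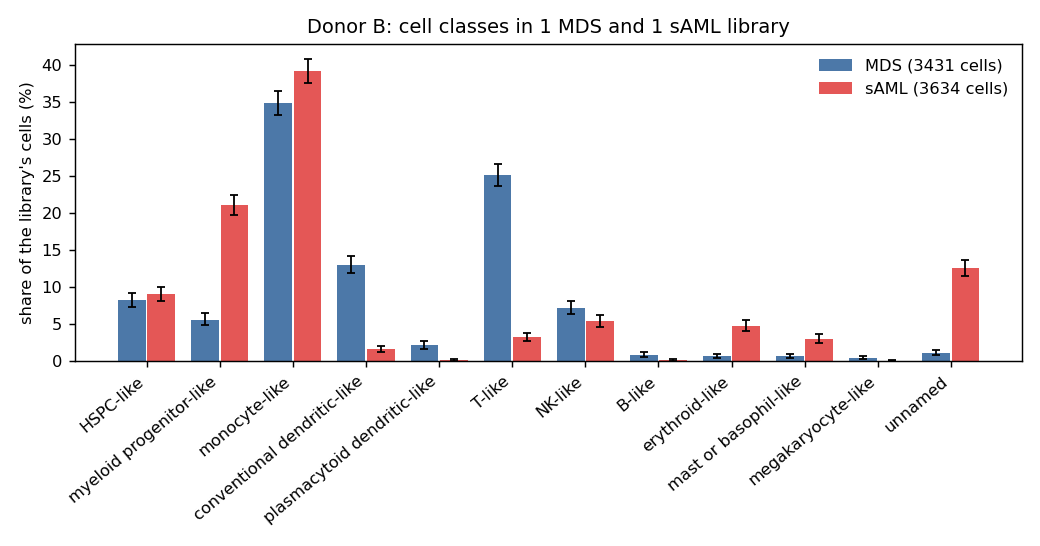
Share of cells (%) in each cell class of donor B, as bars for 1 MDS library of 3431 cells and 1 sAML library of 3634 cells, with exact 95% binomial intervals. Myeloid-progenitor-like cells stood at 5.63% in MDS and 21.0% in sAML, and T-like cells at 25.1% and 3.22%.

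Progenitor-like cells of the sAML library carried more RNA of inflammatory chemokines and of monocytic genes than those of the MDS library, and less RNA of interferon-induced genes. CXCL8, which encodes the neutrophil-attracting chemokine interleukin-8 (ENSG00000169429, GRCh38 chromosome 4, 73740506 to 73743716), stood at 24.3 CPM (UMI counts scaled to the total of the class) in MDS and 201 CPM in sAML, a log2 ratio of 3.05 (2.80 to 3.31). IFI44L, an interferon-induced gene (ENSG00000137959, chromosome 1, 78619922 to 78646145), stood at 55.6 and 7.42 CPM, a log2 ratio of -2.91 (-3.29 to -2.53). The 476 MDS and 1092 sAML cells gave 10580 genes with at least 50 UMIs, and the median log2 ratio over all of them was 0.18. Scaling by TMM or by DESeq2 size factors lowered every ratio in this class by 0.15 or 0.16, and the list medians of this class are to be read against that shift.

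Among the 10 genes with the largest ratios, CXCL3, another neutrophil chemokine (ENSG00000163734, chromosome 4, 74036589 to 74038807), had 17.1 and 77.8 CPM, a log2 ratio of 2.19 (1.88 to 2.51). S100A9 and S100A8 encode the subunits of calprotectin, a protein of monocytes and neutrophils. S100A9 (ENSG00000163220, chromosome 1, 153357854 to 153361027) had 206 and 867 CPM, a log2 ratio of 2.08 (1.99 to 2.17), and S100A8 (ENSG00000143546, chromosome 1, 153390032 to 153391188) had 603 and 1940 CPM, a log2 ratio of 1.69. FCN1, a monocyte lectin gene, had a log2 ratio of 1.69 and SLC2A3, a glucose transporter gene, one of 1.80. The nuclear receptor gene NR4A2 (1.59) and the pseudokinase gene TRIB1 (1.57) completed the set with HIST1H2AJ and HIST1H2AI, a pair of histone H2A genes with 517 and 515 UMIs in sAML and 96 UMIs each in MDS. With each library clustered alone, S100A8, S100A9 and FCN1 turned to log2 ratios of -1.97, -1.66 and -1.83 and the histone genes had 0.12 and 0.40. In myeloid-progenitor-like cells alone NR4A2 had 0.69.

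Among the 10 genes with the smallest ratios, 3 were members of the interferon list, namely IFI44L, MX1 and IFI6. MX1, an antiviral GTPase gene (ENSG00000157601, chromosome 21, 41420304 to 41459214), had 50.8 CPM in MDS and 8.75 in sAML, a log2 ratio of -2.54 (-2.90 to -2.19). IFI6 (ENSG00000126709, chromosome 1, 27666061 to 27672218) had 111 and 42.3 CPM. GBP2, an interferon-inducible GTPase gene outside that list, had a log2 ratio of -1.27. KLF2 (ENSG00000127528, chromosome 19, 16324817 to 16327874) and KLF6, Krüppel-like transcription factor genes, had log2 ratios of -1.58 and -1.10. RHOB, a small GTPase gene (ENSG00000143878, chromosome 2, 20447074 to 20449445), had 203 and 63.6 CPM. TSC22D3, a glucocorticoid-induced gene, had 798 and 317 CPM, and CD52 and PBXIP1 had log2 ratios of -1.40 and -1.22, which came as near to 0 as -0.42 and -0.41 under the alternatives run.

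**Figure D2:**
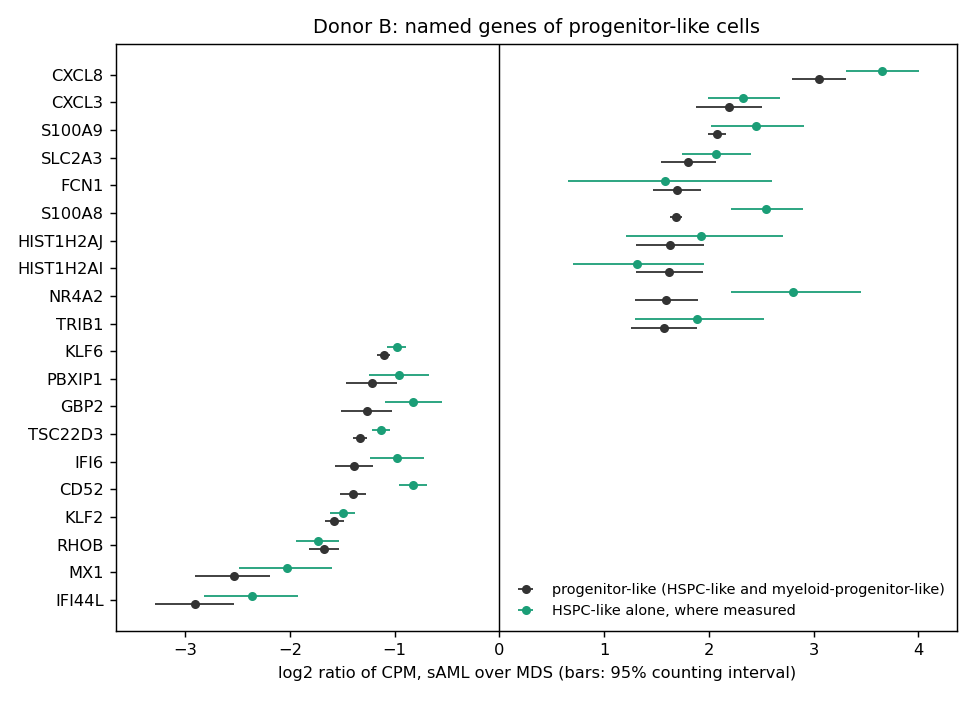
Log2 ratio of CPM, sAML over MDS, for the 20 named genes of donor B progenitor-like cells (dark points) and of HSPC-like cells alone where measured (green points), with 95% counting intervals as bars. CXCL8 stood highest among the progenitor-like points at 3.05 and IFI44L lowest at -2.91.

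The interferon response list had the lowest median of the lists in progenitor-like cells. Its median log2 ratio was -1.24 (bootstrap interval -1.44 to -0.92), below all 10000 random lists matched on expression. Of its 15 measured genes, 8 were at least 2-fold lower in sAML with separate counting intervals and 0 were higher. EPSTI1 had 35.2 and 9.66 CPM, and IFIT3 had 21.0 and 4.58 CPM. The list on NF-kB and inflammation was higher in sAML, with a median of 1.28 (1.14 to 1.48) and a percentile of 100, and 8 of its 12 measured genes were higher. IER3, an early survival gene, had 4.09 and 45.0 CPM (3.46), NFKBIA, the inhibitor that NF-kB itself induces, had 177 and 387 CPM (1.13), and TNFAIP3, another feedback inhibitor, had 5.51 and 21.9 CPM (1.99). BIRC3, an inhibitor of apoptosis, was the 1 member lower in sAML, at 14.6 and 5.19 CPM (-1.49).

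Genes of monocytic maturation had a median of 1.69 (1.52 to 1.73), above all 10000 random lists, and 8 of 11 measured genes were higher. VCAN had 5.86 and 46.4 CPM (2.98), CD36 had 4.98 and 24.6 CPM (2.31) and MNDA had 52.2 and 151 CPM (1.53). T-like cells, which should lack S100A8 and S100A9, held 101 and 73.6 CPM of them in MDS and 182 and 182 CPM in sAML, levels below those of the progenitor-like cells. Primary granule proteins had a median of 0.49 (percentile 99.97), with 3 of 10 genes higher. MS4A3 had 14.6 and 45.0 CPM, RNASE2 had 101 and 229 CPM, and MPO, myeloperoxidase, had 1484 and 2156 CPM (0.54). The granule median was 0.04 (percentile 24.25) in HSPC-like cells alone and -0.16 (2.8) in myeloid-progenitor-like cells alone. Both lay within the range of random lists, so the higher value was seen only in the sum.

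Genes of the G2 and M phases had a median of 1.10 (0.97 to 1.19; percentile 100), with 11 of 15 higher. MKI67, the proliferation marker, had 38.7 and 86.2 CPM (1.16), PLK1, a mitotic kinase gene, had 11.0 and 28.7 CPM (1.38), and HMGB2 had 317 and 493 CPM (0.64). S phase genes had a median of 0.51 (percentile 99.98), with 2 of 15 higher, namely RRM2 (6.40 and 33.3 CPM), a subunit of ribonucleotide reductase, and CLSPN (21.1 and 51.5 CPM), a replication checkpoint gene. Genes of stem cell identity had a median of -0.73 (-0.76 to -0.57; percentile 0), although none of the 11 measured genes reached a 2-fold difference. CD34, the surface marker of HSPC, had 146 and 78.6 CPM (-0.89), SPINK2 had 187 and 110 CPM (-0.77) and HOPX had 248 and 155 CPM (-0.68). The LSC17 list, a published score of leukemic stemness, had a median of -0.35 (percentile 0), with 1 of 15 genes lower.

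These list medians for maturation, granule proteins, cycle and stem cell identity moved with the make-up of the class. HSPC-like cells were 283 of the 476 MDS cells and 328 of the 1092 sAML cells. In HSPC-like cells alone the medians were 0.49 for G2 and M, -0.30 for stem cell identity and 0.06 for LSC17, the last of which turns negative under the TMM and DESeq2 shifts of this class, -0.11 and -0.08. No G2 and M gene was called higher in HSPC-like cells (0 of 5) or in myeloid-progenitor-like cells (0 of 15). The G2 and M medians still lay high among random lists, at percentiles 97.9 and 99.97, although the HSPC-like interval included 0 (-0.07 to 0.77). Stem cell identity stayed low in both, at percentiles 0 and 0.01. Some members of the stem cell, granule and monocytic lists, such as CD34, MPO and S100A8, are also naming markers. Their levels in named classes are therefore not independent of the naming rule. The S phase median was 0.06 in HSPC-like cells (percentile 22.9; 0 of 14 higher) and 0.47 in myeloid-progenitor-like cells (99.8; 3 of 15 higher). Monocytic maturation had 0.99 in myeloid-progenitor-like cells, with 5 of 11 higher. With each library clustered alone, the monocytic maturation and G2 and M medians turned to -1.20 and -0.77, while CXCL8, IFI44L and MX1 stayed within 2.46 to 3.65, -3.29 to -2.36 and -2.80 to -2.03 over all the alternatives run.

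Signalling lists in progenitor-like cells split. Genes induced by the MAPK pathway had a median of 1.05 (percentile 99.94), with 3 of 6 measured genes higher. ETV5, a transcription factor gene of that pathway, had 0.711 and 8.24 CPM (3.53), while DUSP6, a phosphatase gene of its feedback, had 120 and 90.6 CPM (-0.40). Only 3 and 4 MAPK genes were measured in HSPC-like and myeloid-progenitor-like cells alone. The MAPK median thus could not be checked against the make-up of the class. Genes induced by JAK-STAT signalling had a median of -0.11 (percentile 1.64), with SOCS3 higher (9.06 and 30.3 CPM) and SOCS2 (13.9 and 1.22 CPM) and SOCS1 (35.2 and 15.6 CPM) lower. In HSPC-like and myeloid-progenitor-like cells alone that median was 0.08 (33.3) and 0.18 (34.4), within the range of random lists. Targets of p53 had a median of 0.59 (0.48 to 0.84; percentile 99.9), with 4 of 12 higher, among them CDKN1A, the cell cycle inhibitor p21, at 8.35 and 38.04 CPM (2.19) and FDXR at 6.22 and 14.4 CPM (1.22). In HSPC-like cells alone the p53 median was 0.36 (97.4), within that range. HOX genes and their partners had a median of -0.22 (percentile 1.2) with an interval that included 0 (-0.57 to 0.03), and in HSPC-like cells alone one of -0.14 (5.64), within the range of random lists. HOXA5 had 14.8 and 1.93 CPM (-2.93) and HOXA3 had 11.6 and 5.59 CPM (-1.05), whereas HOXA9, a gene of self-renewal in leukemia, had 32.3 and 36.4 CPM (0.17).

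Unfolded protein response genes had a median of 0.43 (percentile 99.2), above the central 95% of random lists, and heat shock genes 0.35 (97.1), within it, each with 0 of 11 members past 2-fold. In HSPC-like cells alone the former had 0.20 (80.9), within that range. The heat shock median hardly moved there, at 0.33, but lay above the narrower random range of those cells (percentile 99.3; upper bound 0.29 against 0.36). A further 7 lists lay within that range in progenitor-like cells. Glycolysis had 0.25 (87.6), the BCL2 family 0.20 (61.2; 0.49 and 98.7, above that range, in myeloid-progenitor-like cells alone), oxidative phosphorylation 0.16 (72.6; -0.0062 with DESeq2 size factors), and MHC class II 0.02 (19.9; -0.13 and -0.15 under TMM and DESeq2 scaling). Spliceosome genes, which include the splicing factors often mutated in MDS, had 0.11 (20.9), AML surface antigens 0.11 (28.3) and immediate early genes 0.11 (42.6), and the median of each of these 3 turned negative under TMM and DESeq2 scaling. Lists for megakaryocyte-erythroid priming, naive or memory T cells, cytotoxicity, inhibitory receptors of T cells and hemoglobin had fewer than 5 measured genes in this class.

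HSPC-like cells alone, 283 in MDS and 328 in sAML, showed the same opposition of inflammatory and interferon genes. IER3 had 2.31 and 55.0 CPM, a log2 ratio of 4.57 (3.57 to 5.81), CXCL8 had 21.6 and 271 CPM (3.65), and NR4A2 had 7.496 and 52.3 CPM (2.80). IFI44L had 71.2 and 13.9 CPM (-2.36), MX1 had 61.1 and 14.9 CPM (-2.03), RHOB had 235 and 70.4 CPM (-1.74), SELENOP had 64.6 and 19.7 CPM (-1.71) and KLF2 had 608 and 215 CPM (-1.498). S100A8 (24.2 and 142 CPM) and S100A9 (14.7 and 80.3 CPM) were also among the 5 largest ratios but stood below their level in T-like cells of the same library, so they were not told apart from free RNA. The list on NF-kB and inflammation had a median of 1.28 (1.21 to 1.48) with 9 of 12 genes higher, among them NFKBIA (225 and 528 CPM), CXCL2 (167 and 402 CPM) and ICAM1, an adhesion molecule gene (2.60 and 15.5 CPM). The interferon list had a median of -0.99 (-1.19 to -0.80) with 6 of 12 genes lower. The 14 AML surface antigens had a median of 0.28 (percentile 96.3), within the range of random lists, and 3 of them were higher, namely TNFRSF4 (4.90 and 28.3 CPM), IL2RA (4.61 and 14.9 CPM), the receptor subunit CD25, and CD7 (11.0 and 24.3 CPM).

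Myeloid-progenitor-like cells alone, 193 in MDS and 764 in sAML, had CXCL3 (5.56 and 50.8 CPM), VCAN (9.73 and 70.0 CPM), CXCL8 (28.7 and 158 CPM), SERPINA1 (11.6 and 59.3 CPM) and RRM2 (11.1 and 50.6 CPM) as the largest ratios, between 2.19 and 3.19. The smallest were those of IFI6 (126 and 36.7 CPM), RHOB (153 and 59.3 CPM), the ubiquitin-like interferon gene ISG15 (85.2 and 35.5 CPM), KLF2 (316 and 136 CPM) and TSC22D3 (550 and 243 CPM), between -1.79 and -1.18. The list on NF-kB and inflammation had a median of 1.59 with 6 of 11 genes higher, and the interferon list one of -1.13 with 7 of 13 lower. Primary granule proteins had a median of -0.16 (percentile 2.8) in these cells, opposite in sign to the summed class.

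**Figure D3:**
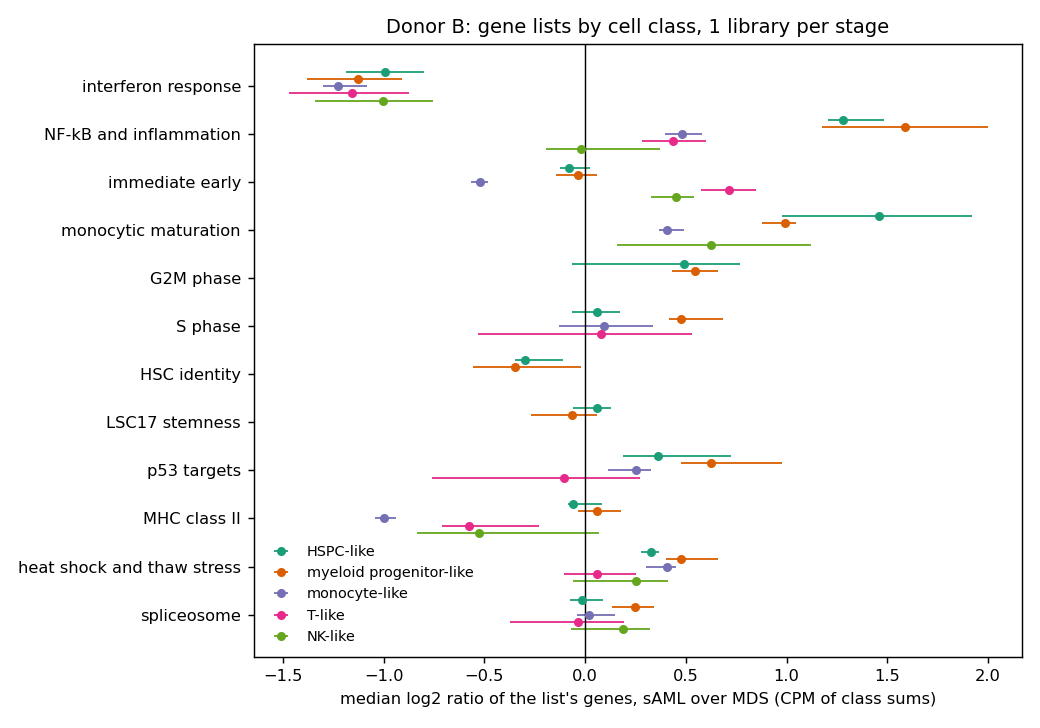
Median log2 ratio of CPM, sAML over MDS, of 12 gene lists in 5 cell classes of donor B, each point 1 list in 1 class with its 95% bootstrap counting interval. The interferon points lay between -1.23 and -0.99, and the NF-kB points between -0.02 in NK-like cells and 1.59 in myeloid-progenitor-like cells.

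Monocyte-like cells of the sAML library had less RNA of interferon-induced, MHC class II and immediate early genes and more RNA of CLU, IL1R2 and HP than those of MDS. The interferon list had a median log2 ratio of -1.23 (-1.30 to -1.08; percentile 0), with 9 of 16 genes lower, among them IFI44L (209 and 58.3 CPM) and MX1 (205 and 69.1 CPM). MHC class II genes, which present antigen to helper T cells, had a median of -1.0005 (-1.04 to -0.94; percentile 0), with 4 of 7 lower. CD74, the invariant chain, had 11503 and 6262 CPM (-0.88), HLA-DRA had 3057 and 1587 CPM (-0.95), and CIITA, the master regulator of the group, had 37.3 and 18.1 CPM (-1.04). The median over all 9540 measured genes was 0.11 in this class, and TMM and DESeq2 scaling lowered every ratio by 0.12 and 0.14. The class differed in make-up between the stages, since the 2 monocyte-like clusters with a larger share in MDS held 978 of its 1195 MDS cells and 144 of its 1423 sAML cells.

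CLU, the chaperone clusterin, had 8.14 and 94.8 CPM in monocyte-like cells, a log2 ratio of 3.54. IL1R2, the decoy receptor for interleukin-1, had 17.8 and 119 CPM (2.74), ADM, adrenomedullin, 13.4 and 56.3 CPM (2.07), CR1, a complement receptor, 21.7 and 73.5 CPM (1.76), and HP, haptoglobin, 22.4 and 75.3 CPM (1.75). At the other end stood AREG, the growth factor amphiregulin, with 737 and 124 CPM (-2.58), followed by IFIT3 (111 and 24.8 CPM), IFITM1 (214 and 51.9 CPM), GIMAP4 (104 and 25.6 CPM) and CMPK2 (50.8 and 13.9 CPM), of which IFIT3, IFITM1 and CMPK2 are interferon-induced. Immediate early genes had a median of -0.52 (-0.56 to -0.48; percentile 0). EGR1 had 547 and 241 CPM (-1.18), NR4A1 had 113 and 39.8 CPM (-1.499) and FOS had 6647 and 3597 CPM (-0.89).

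Inflammatory and monocytic genes were higher by less in monocyte-like cells than the interferon list was lower. The list on NF-kB and inflammation had a median of 0.48 (percentile 100), with 4 of 14 genes higher, CXCL8 among them at 178 and 422 CPM (1.24), and BIRC3 lower. Monocytic maturation had 0.41 (percentile 100), with VCAN at 1066 and 2442 CPM (1.20), S100A8 at 15386 and 26671 CPM (0.79) and FCN1 at 2521 and 2030 CPM (-0.31). The MAPK list had a median of 0.86 (99.5), heat shock genes 0.41 (99.6), JAK-STAT genes 0.34 (91.6, within the range of random lists) and glycolysis 0.31 (99.5). Granule genes had 0.88, with MPO at 23.3 and 64.3 CPM, but T-like cells held 20.5 and 32.9 CPM of MPO, so free RNA was not excluded as a part of it.

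T-like cells of the sAML library, 117 against 862 in MDS, had more RNA of cytotoxic and immediate early genes and less of interferon-induced and naive T cell genes. The cytotoxicity list had a median log2 ratio of 0.88 (0.77 to 0.97; percentile 100), with 4 of 12 genes higher. GNLY, the pore-forming granulysin, had 653 and 1485 CPM (1.19), GZMB, granzyme B, had 51.8 and 124 CPM (1.26), FGFBP2 had 69.3 and 175 CPM (1.33) and IFNG, interferon gamma, had 32.9 and 126 CPM (1.94). Genes of naive or memory cells had a median of -0.41 (percentile 0.47), with the homing receptor gene CCR7 at 114 and 35.4 CPM (-1.69). The cytotoxic group was 175 of the 862 MDS cells and 63 of the 117 sAML cells, so the class differed in make-up between the stages.

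The interferon list had a median of -1.16 in T-like cells (percentile 0), with 9 of 15 genes lower, among them MX1 (173 and 70.8 CPM; -1.29). Immediate early genes had a median of 0.71 (0.58 to 0.85; percentile 100), which ranged from 0.35 to 0.79 over the alternatives run. ATF3 had 32.1 and 147 CPM (2.19), IER2 had 477 and 1381 CPM (1.53) and JUN had 1310 and 2980 CPM (1.19). NFKBIA had 296 and 954 CPM (1.69) and TNF had 29.5 and 109 CPM (1.88), within a list median of 0.44 (99.9) that ranged from 0.13 to 1.23 over the alternatives run. The inhibitory receptor list had a median of 0.05, with TOX, a transcription factor gene of exhausted T cells, at 15.8 and 43.0 CPM (1.44). SLAMF7 had 17.5 and 63.2 CPM (1.85). The smallest ratios were those of MAP3K1 (56.9 and 7.59 CPM; -2.91, -5.20 to -1.33), the chemokine receptor gene CCR4 (70.2 and 10.1 CPM), ADAM19 (70.2 and 15.2 CPM), ITM2C (97.1 and 22.8 CPM) and the kinase gene TXK (53.05 and 12.6 CPM), each resting on 3 to 9 UMIs in sAML.

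NK-like cells, 248 in MDS and 196 in sAML, had a median of -1.01 for the interferon list (percentile 0), with 5 of 10 genes lower. MX1 had 158 and 29.9 CPM (-2.40), IFI44L had 120 and 23.9 CPM (-2.33), CRTAM had 58.2 and 14.0 CPM (-2.06), AREG had 717 and 215 CPM (-1.74) and XCL1, a chemokine gene of NK cells, had 640 and 193 CPM (-1.73). The XCL1-rich NK group made up 3.03% and 1.57% of the cells, and the FCGR3A-rich group 4.197% and 3.82%. Immediate early genes had a median of 0.45 (0.33 to 0.54; percentile 99.97), with JUN at 584 and 1959 CPM (1.75) and ATF3 at 19.4 and 79.8 CPM (2.04), and HIST1H1C had 31.02 and 118 CPM (1.92). The cytotoxicity list had a median of 0.19, with 0 of 12 past 2-fold and CCL5 at 1955 and 3072 CPM (0.65). HBB, the beta globin gene, had the largest ratio (29.7 and 411 CPM; 3.79), but 3 of the 196 sAML cells held 191 of its 206 UMIs.

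Conventional-dendritic-like cells, 446 in MDS and 59 in sAML, had IFIT3 at 63.2 and 9.28 CPM (-2.77), IFI44L at 148 and 22.3 CPM (-2.73), REPIN1 at 55.7 and 9.28 CPM (-2.59) and FCER1A, the IgE receptor gene that marks these cells, at 318 and 102 CPM (-1.64). HBB had 131 and 7.42 CPM, and 3 MDS cells held 581 of the 615 HBB UMIs of all dendritic-like cells. MAFF (11.8 and 59.4 CPM), IL1R2 (28.9 and 119 CPM), CARHSP1 (14.1 and 55.7 CPM), MS4A4A (46.7 and 176 CPM) and CXCL8 (16.3 and 59.4 CPM) had log2 ratios between 1.87 and 2.33. Over all dendritic-like cells, where the plasmacytoid share was lower in sAML, GZMB, which plasmacytoid cells also express, had 79.3 CPM in MDS and 0 UMIs in sAML, and MZB1 had 74.3 and 5.27 CPM (-3.82, -6.10 to -2.26). The interferon list had a median of -1.10 there, with 7 of 16 genes lower.

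Over all kept cells, hemoglobin genes had a median of 1.95 (6 of 6 higher), megakaryocyte-erythroid priming genes 0.75 (4 of 12 higher), G2 and M genes 1.92 (14 of 15 higher), naive or memory T cell genes -2.15 (6 of 8 lower), inhibitory receptor genes -0.75 (3 of 8 lower), MHC class II genes -1.41 (7 of 7 lower) and interferon genes -1.47 (14 of 16 lower). The erythroid gene CA1, encoding carbonic anhydrase 1, had 10.6 and 126 CPM (3.57), and PRG2 (3.52), ALAS2 (2.70), CXCL3 (2.55) and CLC (2.52) followed. The T cell genes IL7R (202 and 30.9 CPM; -2.71), CD3G (-2.46) and LTB (-2.38) and the interferon genes IFIT3 (-2.44) and IFI44L (-2.38) were lowest. These sums carried the differences in cell shares as well as those within classes.

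The second donor, here donor A, had the MDS and the sAML marrow tagged with antibody hashtags and run in 1 lane, and no file or label used here ties a hashtag to a stage, so its 12886 kept cells were described as 1 pool. T-like cells made up 35.3% of them, erythroid-like cells 18.3%, NK-like cells 6.81%, progenitor-like cells 6.74% (868 cells, of which 796 HSPC-like), monocyte-like cells 5.87%, B-like cells 4.35%, megakaryocyte-like cells 1.99% and dendritic-like cells 0.660%. The megakaryocyte-like share was 0.279% at resolution 0.5 and 0.310% at resolution 2.0, where a cluster of 216 cells was named mast or basophil instead. All 85 dendritic-like cells of the pool were plasmacytoid-dendritic-like, unlike in donor B. Unnamed cells were 19.9%. The pool held 6 hashtags with counts, numbered 1, 2, 3, 4, 5 and 7, although the labels name 2 samples. Hashtags 1, 4 and 5 marked most of the cells kept with a single hashtag, with 3809, 1478 and 4080 cells.

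Cell classes differed between the hashtags. Progenitor-like cells were 33.3% of the cells with hashtag 2 and 32.6% of those with hashtag 4, against 5.69% with hashtag 5, 1.85% with hashtag 7 and 0.210% with hashtag 1. Hashtag 3 had 0 progenitor-like cells of 371, which allows up to 0.809%. Monocyte-like cells were 29.4% with hashtag 4 and between 1.23% and 8.63% with the others. T-like cells were 55.8% with hashtag 1, 58.2% with hashtag 3 and 38.8% with hashtag 5, against 15.3% with hashtag 4 and 2.15% with hashtag 2. Erythroid-like cells were 14.6% with hashtag 5 and between 1.69% and 8.60% with the others, and of the 2420 kept cells without a hashtag above its threshold 64.3% were erythroid-like. Those were 1557 of the pool's 2360 erythroid-like cells, so the classes were not tagged equally. All shares by hashtag are therefore shares of tagged cells and may differ from those of the tagged samples.

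**Figure D4:**
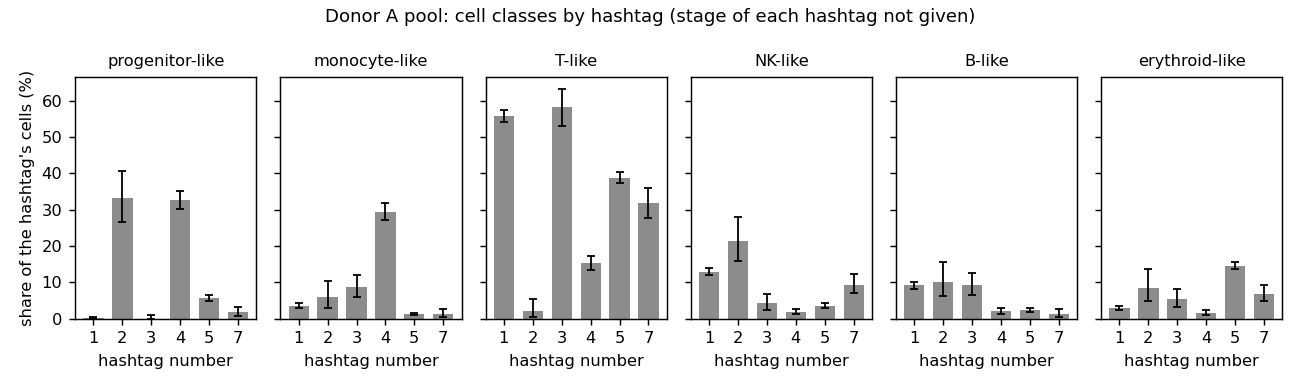
Share of each hashtag's cells (%) in 6 cell classes of the donor A pool, as bars with exact 95% binomial intervals, by hashtag number; the stage of a hashtag is not given. Progenitor-like cells stood at 33.3% and 32.6% for hashtags 2 and 4, and at most 5.69% for the others. The 2420 kept cells without a hashtag above its threshold, mostly erythroid-like, are not shown.

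Some surface protein counts in the pool differed between the classes named from RNA, while many tags were nearly flat. CD235a, glycophorin A of red cell precursors, had a median of 311 UMIs in erythroid-like cells against 74 in T-like cells. CD71, the transferrin receptor, had medians of 189 and 51 in these classes. CD34 protein had a median of 50 UMIs in HSPC-like cells against 33 in T-like cells, and CD11b one of 76 in monocyte-like cells against 50. CD123, the interleukin-3 receptor, had a median of 70 in dendritic-like cells, all of them plasmacytoid-dendritic-like, against 46 in T-like cells. CD3 protein had a median of 122 UMIs in T-like cells and 115 in NK-like cells, a narrow margin over its background. Margins over T-like cells were also narrow for CD14 in monocyte-like cells (43 against 39) and CD117 in HSPC-like cells (37 against 36). The same held in NK-like cells for CD56 (54 against 51) and CD16 (13 against 12).

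Gene lists in T-like cells also differed between hashtags. Immediate early genes summed to 17707 CPM with hashtag 1, 13402 with hashtag 5 and between 8011 and 9823 with hashtags 3, 4 and 7. Genes of NF-kB and inflammation summed to 2710 CPM with hashtag 1 and 863 with hashtag 5. In HSPC-like cells, immediate early genes summed to 11298 CPM with hashtag 2, 5404 with hashtag 4 and 4773 with hashtag 5. No stage was assigned to any of these values.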

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

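Of the tests in this part, the count of T cell transcripts in all deposited barcodes was written before its result was seen. All the others were chosen afterwards.

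Interferon-induced genes were lower in sAML in progenitor-like, monocyte-like, T-like and NK-like cells of donor B, with list medians of -1.24, -1.23, -1.16 and -1.01. Library scaling was argued against, since the list lay at percentile 0 of 10000 expression-matched random lists in each of the 4 classes. Free RNA of monocytes was argued against too, since in MDS T-like cells the interferon genes stood at a median of 56.9% of their monocyte-like level and monocytic genes at 0.893%, a ratio of 63.7. Keeping cells with at least 1000 UMIs or at most 10% mitochondrial UMIs left medians of -0.89 or lower in all 4 classes. A difference in interferon exposure of the marrow between the samplings may account for the pattern, but stage, treatment, infection and handling were not separable with 1 library per stage.

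Genes of NF-kB and inflammation were higher in sAML in HSPC-like cells, with a median of 1.28. Monocyte RNA in these droplets, free or from doublets, was argued against, since the NF-kB genes stood at a median of 61.2% of their monocyte-like level and monocytic genes at 0.529%, a ratio of 116. Stress in handling cannot be told apart from a difference between the stages, because the immediate early list lay low at percentile 3.58 and the heat shock list high at percentile 99.3. A biological difference between MDS and sAML progenitors remains possible and untested.

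T-like cells made up less of the sAML library. Dilution by other cells alone was argued against, since the ratio of T-like to NK-like cells was 3.48 in MDS and 0.597 in sAML, a ratio of 0.172 (0.13 to 0.227). Before the filters used here, 19.6% and 5.74% of the deposited barcodes had at least 2 UMIs of CD3D, CD3E, CD3G and CD2. That ratio of 0.293 (0.257 to 0.333) argued against loss to these filters as the whole of the difference. It was higher than the ratio of T-like shares among kept cells, 0.128, which is a different measure, so a part was not excluded. Loss at cell calling could not be seen, since the deposited barcodes had already been filtered to called cells. A smaller T cell compartment in the sAML marrow may lie behind the pattern, and unequal survival of T cells in freezing and thawing was not tested.

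Antibody features that the donor B comparisons did not use held 742 UMIs in the MDS library and 1090 in the sAML library, above the limit that a count of 0 allows. CD71 antibody UMIs numbered 93 in the 23 erythroid-like cells of MDS, of 227 in all kept cells. In sAML they numbered 377 in the 173 erythroid-like cells, of 593 in all kept cells. CD34 antibody UMIs did not gather in progenitor-like cells. There were 2 in the 476 such cells of MDS, of 64 in all kept cells, and 19 in the 1092 of sAML, of 60. Whether these libraries were stained, or the counts came from RNA reads that match a tag, was not determined. The immediate early list went in opposite directions between classes, with medians of 0.71 in T-like cells, 0.45 in NK-like cells and -0.52 in monocyte-like cells, and the difference between the classes was not tested.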

How the results depend on the processing

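Scrublet's own threshold, the minimum of 1000 UMIs, counting unnamed clusters with their best class or macrophage-named clusters as monocyte-like, and the values for HSPC-like, myeloid-progenitor-like and pool megakaryocyte-like cells were added after the data were seen, and the other alternatives were planned. Among the shares of 8 donor B classes, 77 of 82 alternative values kept their sign and 46 stayed within the counting interval of the reported value. Among the 6 lead list results, 94 of 96 kept their sign and 62 stayed within it. Other lists kept it in 373 of 402 values and named genes in 317 of 320. These counts are weak evidence of stability, since the alternatives draw on the same 2 libraries and named genes were chosen for extreme ratios. Some share values could hardly move. Counting unnamed clusters with their best class after joint clustering left 6 of the 8 shares unchanged, and Scrublet's own threshold marked only 7 MDS and 0 sAML barcodes. Of 24 values of pool shares, 15 stayed within the interval of the reported share. Interferon medians stayed negative throughout, from -1.40 to -0.83 in progenitor-like, -1.37 to -0.89 in monocyte-like, -1.22 to -1.09 in T-like and -1.23 to -0.98 in NK-like cells. MHC class II in monocyte-like cells ranged from -1.23 to -0.59, and cytotoxicity in T-like cells from 0.82 to 0.94. Depth limits classes under 50 cells and genes under 50 UMIs, and 1 library per stage limits every comparison. The edgeR stage test and its 4 alternatives were not run. Except where stated, the cause was not tested.

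For the share differences in percentage points, the progenitor-like value of 16.2 was 27.8 with Scrublet's own threshold, 27.9 with doublets kept, 18.3 with at least 500 genes, 18.4 with at least 1000 UMIs, 19.5 at 10% mitochondrial UMIs, 25.8 and 26.3 at resolutions 0.5 and 2.0, and 25.9 with unnamed clusters in their best class. Each library clustered alone gave 0.916, and 27.6 with unnamed clusters in their best class. The drop thus lay in unnamed clusters, among them sAML clusters of 459, 293 and 219 cells. Which criterion of the naming rule each of these missed was recorded and is not given here. The monocyte-like value of 4.33 was 1.21 with Scrublet's threshold, 1.20 with doublets kept, 8.68 at 10% mitochondrial UMIs, 0.0858 at resolution 2.0 and 0.570 clustered alone, and turned to -8.62 with at least 500 genes, -2.15 with at least 1000 UMIs and -0.567 clustered alone with best classes. The first is due to naming, since a cluster of 7 MDS and 313 sAML cells was named macrophage, and counting it as monocyte-like gave 1.0051. The second is 1.13 with best classes. The dendritic-like value of -13.4 was -15.2 with 500 genes, -14.8 with 1000 UMIs, -11.8 at resolution 0.5 and -11.5 at 2.0. The T-like value of -21.9 was -20.2 with 500 genes, -18.9 with 1000 UMIs, -17.6 at 10% mitochondrial UMIs and -19.2 at resolution 2.0. The NK-like value of -1.83 was -0.0474 clustered alone, with or without best classes. The B-like value of -0.735 turned to 0.945 with best classes and 3.25 clustered alone with best classes, both by construction, since an unnamed cluster joined the class. The erythroid-like value of 4.09 was 5.86 with Scrublet's threshold and with doublets kept, 3.29 with 500 genes and 5.02 at 10% mitochondrial UMIs.

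For list medians in progenitor-like cells, TMM and DESeq2 scaling gave 0.95 and 0.94 for G2 and M (reported 1.10), -0.88 and -0.89 for stem cell identity (-0.73), 1.13 and 1.11 for NF-kB (1.28), 0.44 and 0.43 for p53 targets (0.59), and turned AML antigens to -0.038 and -0.0497, immediate early genes to -0.038 and -0.0500 and spliceosome genes to -0.043 and -0.054, by construction as a common shift. Oxidative phosphorylation turned to -0.0062 with DESeq2. HSPC-like cells alone gave 0.49 for G2 and M, -0.30 for stem cell identity, 1.46 for monocytic maturation and 0.36 for p53 targets, and turned LSC17 to 0.0601, immediate early genes to -0.081 and spliceosome genes to -0.017. Myeloid-progenitor-like cells alone gave 0.54, -0.35, 1.59 for NF-kB and 0.99 for monocytic maturation, and turned immediate early genes to -0.035 and granule genes to -0.16. Libraries clustered alone gave -0.24 for stem cell identity and turned G2 and M to -0.77, monocytic maturation to -1.20, LSC17 to 0.12, immediate early genes to -0.14, FCN1 to -1.83, S100A8 to -1.97 and S100A9 to -1.66, and with best classes gave -0.79 for stem cell identity, -0.83 for interferon (-1.24) and 1.77 for monocytic maturation (1.69). NF-kB was 1.58 with 20 UMIs or 1 UMI per gene, 1.51 with Scrublet's threshold, 1.62 and 1.53 at resolutions 0.5 and 2.0 and 1.60 with best classes. Monocytic maturation was 1.5022 with Scrublet's threshold, 1.42 with doublets kept, 1.98 with 1000 UMIs, 1.45 and 1.42 at resolutions 0.5 and 2.0 and 1.75 with best classes.

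For pool shares in %, a limit of 10% mitochondrial UMIs gave 4.69 for NK-like (6.81), 36.9 for T-like (35.3) and 20.6 for erythroid-like cells (18.3). Doublets kept gave 5.95 for NK-like and 7.23 for monocyte-like cells (5.87). Resolution 0.5 gave 38.8 for T-like, 21.7 for erythroid-like and 0.0931 for progenitor-like cells (6.74), the last because a cluster of 1075 cells closest to HSPC and mast cells stayed unnamed, and resolution 2.0 gave 37.7 for T-like cells.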

Other observations

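No test was run on the values in this part, which were chosen for mention after they were seen. Among monocyte-like cells, a group led by HP, CLU, MCEMP1 and SERPINB2, genes of secreted proteins and of myeloid cells, held 32 MDS cells (0.933%) and 176 sAML cells (4.84%). A group led by CDA, QPCT, PLBD1 and S100A12 held 454 MDS cells (13.2%) and 113 sAML cells (3.11%). An unnamed group led by ACY3, DNTT, JCHAIN and MS4A1, of which DNTT is the terminal transferase of lymphoid precursors, held 33 MDS and 96 sAML cells and scored about alike for B cells and B precursors. Median UMIs per cell were 6541 and 3330 in monocyte-like cells, 10822 and 5352 in myeloid-progenitor-like cells and 2500.5 and 3430 in T-like cells. In dendritic-like cells, heat shock genes had a median log2 ratio of 0.63 and S phase genes 1.07, and MHC class II genes -0.20.

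In the donor A pool, an unnamed group of 932 cells was led by GZMH, CCL5, GZMA, CD8A and CD8B, genes of cytotoxic T cells, and scored close to both NK and T cells. A group of 487 cells was led by JCHAIN, ACY3, DNTT and VPREB1, genes of lymphoid precursors and plasma cells, and another of 431 cells by ALDH1A1, FAM178B, CNRIP1 and NMU. The megakaryocyte-like group was led by PF4 and PPBP, platelet chemokine genes, together with the mast cell tryptase genes TPSB2 and TPSAB1. HLA-DR protein had medians of 165 UMIs in B-like, 149 in monocyte-like and 121 in T-like cells. CD45RA protein had medians of 60 in NK-like, 58 in B-like and 34 in HSPC-like cells, and CD45 protein 38 in HSPC-like and 74 in monocyte-like cells. Heat shock genes summed to 7342 CPM in T-like cells with hashtag 1 and to between 3071 and 4677 CPM with hashtags 3, 4, 5 and 7, and in NK-like cells to 7537 CPM with hashtag 1 and 3397 CPM with hashtag 5.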
